A study of Mus musculus with 5 samples.

How the data were processed

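Single-cell RNA sequencing of mouse dorsal skin was analysed in 5 libraries. Whole, unsorted skin of female mice at postnatal day 46 gave 4 libraries, 2 from a control genotype and 2 from a genotype that the labels write with Smo+/-. GFP-positive cells sorted at postnatal day 50 gave the other library. All mice carried Lepr-Cre, a recombinase under control of the leptin receptor locus, and mTmG, a Rosa26 reporter that switches from membrane tomato to membrane GFP where the recombinase has acted. The labels' protocols call the 2 libraries of a genotype technical replicates, so p-values here measure only the spread between these preparations and not that between animals. The labels name the control in 2 ways, with and without Smo after the reporter, and do not say how the Smo allele was changed.

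The deposited matrices hold raw UMI counts per gene and cell barcode, already restricted by the authors to barcodes called as cells. The counts were made with Cell Ranger, whose versions 2.1.1 and 3.1.0 are both named in the submitters' processing notes together with Seurat 3.2.2, Scanpy 1.6.0 and the builds mm10 and GRCm38. Per the file headers, the unsorted libraries came from Cell Ranger 3.1.0. Per the labels' protocols, sorted cells were captured with version 2 and unsorted cells with version 3 of the 10x Genomics chemistry that tags 3′ ends, so levels were not tested between them. The deposited gene lists hold 28001 features in unsorted libraries, among them the reporters eGFP, YFP and tomato, and 31054 in the sorted library, among them eGFP. Coordinates are those of GRCm38 in the GENCODE annotation used here, and all 146 genes looked up were matched by their identifier.

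Cells were kept with at least 500 and at most 8000 genes (sorted library, at least 300) and at most 10% mitochondrial UMIs. Doublets were called in each unsorted library with the scrublet implementation of scanpy 1.11.5, which removed 202 and 184 control and 177 and 174 mutant barcodes. No doublet caller was run on the sorted library. Counts were scaled to 10000 per cell, log-transformed and clustered on 2000 variable genes with 40 principal components (sorted library, 15), 15 neighbours and the Leiden algorithm (leidenalg 0.10.2) at resolution 1.0. Mitochondrial genes, the reporters, Lepr, Smo and part of the Hedgehog target list, including Gli1, Ptch1 and Hhip, were left out of the variable genes. Some genes that were tested and counted are not reported here by name. The plan had been to leave out the whole Hedgehog target list of 12 genes. Of the members not left out, Bcl2 and Osr2 were among the variable genes used, a departure found only after the results were seen, and a clustering without the whole list was therefore added. The clustering gave 38 clusters of unsorted and 6 of sorted cells. Mesenchymal clusters of the unsorted libraries were clustered again on 30 components. A cluster was called X-like from marker lists of 22 cell types when at least 3 markers of the type (5 for hair follicle keratinocytes) were detected in at least a share of 0.1 of its cells at a log2 fold of at least 1 over the other clusters. Clusters led by genes of another type, with many UMIs and markers of another lineage, or with few UMIs and no marker among their leading genes, stayed unnamed. The marker lists were planned, but these naming thresholds were set with the clusters in view, and the follicle rule after a first naming. Class names are therefore rebuilt here and may differ from those of the study.

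UMI counts of kept cells were summed per library and class, and classes with at least 20 cells in every unsorted library were compared. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test, genotype as the only term). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with an absolute log2 fold change of at least 1. CPM are UMI counts scaled to the sum of the class, on the TMM scale where they stand beside a fold change, and on the plain scale per library elsewhere. Fold changes are those of the fitted model, and log2 CPM for the list tests carried a prior count of 2. Lepr was also compared between papilla-like and fibroblast-like sums with the library as a block, and effects were compared between these classes with an interaction term. Sets were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for 23 gene lists and 22 marker lists wherever at least 3 members were tested, which gave 168 tests adjusted as 1 family. Camera with an estimated correlation and fry were run beside it. With an estimated correlation no list in any class passed, the smallest adjusted p being 0.602. Shares of cells were compared with a two-sided exact permutation test, whose smallest possible p with 2 against 2 libraries is 0.333. Exact 95% binomial (Clopper-Pearson) and Poisson intervals cover counting error only, and a count of 0 allows up to 3 counts. For shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out.

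The genes named in each of the 4 main class comparisons were set by a rule. It took the 10 largest rises and 10 largest falls among called genes with at least 20 CPM in the higher genotype, with both mutant libraries beyond both control libraries, and with a class level of at least 0.25 of that in the highest class, leaving out predicted, mitochondrial and ribosomal protein genes. Up to 4 called members of each list were added, and Smo, Lepr, Gli1, Ptch1, Hhip, Gli2, Gli3 and Scube3 were among those always named. Groups, tests, lists, markers, cell filters and this rule were fixed before the data were examined.

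The test was first run on simulated counts with known changes, drawn from the means, library sizes and trended dispersions of each class. These counts follow the model that the test itself assumes, without a spread of dispersion between genes of like level. The rates below may therefore be better than those on real counts. In fibroblast-like sums it called 2.04% of genes changed 1.5-fold, 50% at 2-fold and 100% at 4-fold and 8-fold. In papilla-like sums it called 6.12% at 1.5-fold, 44.9% at 2-fold, 95.8% at 4-fold and 100% at 8-fold. In hair follicle keratinocyte-like sums it called 0% at 1.5-fold, 52.1% at 2-fold, 98% at 4-fold and 100% at 8-fold. In basal keratinocyte-like sums it called 0% at 1.5-fold, 36.7% at 2-fold, 98% at 4-fold and 100% at 8-fold. Unchanged genes called numbered 1, 4, 0 and 2 in these classes. A call needs a log2 fold change of at least 1, so the low shares at 1.5-fold and 2-fold largely reflect that minimum. Without it, 57.1%, 61.2%, 64% and 76% of genes changed 1.5-fold passed in these classes. At 2-fold, 74%, 81.6%, 75% and 79.6% passed without it.

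Alternatives were RLE size factors, the replicate number as a block, no low-count filter, each library left out in turn, DESeq2 1.42.0, no fold minimum, glmTreat against a log2 fold of 1, stricter cell filters, doublets kept, Leiden resolutions of 0.6 and 1.4, and thinning to 1000 UMIs. Leaving out mesenchymal sub-clusters of which at most 5% of cells came from 1 genotype, the clustering without the whole Hedgehog list, the crossed block and the Lepr comparison within mutant libraries alone were added after seeing the data. The sub-clusters were picked by genotype, so leaving them out can by itself shrink a difference between genotypes and is no independent check. Libraries of a genotype differed by more than Poisson noise of single UMIs, and were kept as separate samples. The chi-square per degree of freedom over genes was 4.07 in control and 4.33 in mutant sums of all cells. It counts UMIs as independent draws, although they are grouped in cells. The draw of cells or preparation alone may give such a spread, so it does not show that the libraries came from separate animals.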

Results

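Gene expression was measured by single-cell RNA sequencing in 5 libraries of mouse dorsal skin. Whole skin at postnatal day 46 gave 2 control and 2 mutant libraries, and GFP-positive cells sorted at postnatal day 50 gave 1 library. Throughout, n = 2 counts libraries, which the labels' protocols call technical replicates, and not animals. The deposited files held 10748 and 11072 barcodes in the control, 11563 and 11816 in the mutant and 455 in the sorted library. Their totals were 163044933 and 171197845 UMIs in the control, 152475023 and 147245343 in the mutant and 1138206 in the sorted library. After filtering, 8076 and 8216 control, 8368 and 8644 mutant and 432 sorted cells remained. Kept cells had a median of 9460 and 9727 UMIs in the control, 8452 and 8269 in the mutant and 2209 in the sorted library.

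Papilla-like and fibroblast-like cells took larger shares of the mutant than of the control libraries, and keratinocytes smaller ones. The dermal papilla is the mesenchymal cluster at the base of the follicle that signals to the epithelium. Papilla-like cells made up 6.24% ± 0.219 (SD, n = 2) of control and 15.2% ± 0.566 (SD, n = 2) of mutant cells. Fibroblast-like cells made up 6.63% and 11.8%, basal keratinocyte-like cells 23.0% and 16.7%, suprabasal keratinocyte-like cells 13.1% and 8.80%, and hair follicle keratinocyte-like cells 8.32% and 5.59%. The two-sided exact permutation test gave p = 0.333 for these 5 classes, the smallest value possible with 2 libraries against 2. Unnamed clusters held 10.7% of control and 11.7% of mutant cells. The papilla share cannot be read as a change in cell number, since 7 of the 17 markers that define the class rose and 1 fell within it. Its sub-clusters also included 3 held almost wholly by 1 genotype, with 2 control against 277 mutant cells, 1 against 578, and 147 against 3. A fibroblast-like sub-cluster held 4 control and 502 mutant cells. Without these 4 sub-clusters, an alternative added after the data were seen, the shares were 5.37% and 11.1% for papilla-like and 6.66% and 9.64% for fibroblast-like cells. The follicle class held 3.12% and 2.22% at Leiden resolution 0.6, 3.12% and 2.21% at 1.4, and 3.12% and 2.22% with the whole Hedgehog list left out of clustering, also added after the data were seen.

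Smo, the membrane protein that passes the Hedgehog signal into the cell, was not called changed in any of the 4 main classes. The labels name it as the gene altered in the mutant. In fibroblast-like cells its TMM-scaled level was 39.5 and 45.1 CPM in the control and 49.5 and 42.2 CPM in the mutant libraries (log2 change 0.12 ± 0.104, SE, edgeR adjusted p = 0.515). In papilla-like cells it was 32.4 and 34.5 CPM in the control and 42.0 and 42.4 CPM in the mutant libraries, a log2 change of 0.33 ± 0.0975 (edgeR adjusted p = 0.0118) that stayed under the fold minimum. Reads that tag the 3′ end of Smo (chromosome 6, 29735503 to 29761365 on the plus strand, GRCm38) may not show an allele changed elsewhere in the gene, so these levels do not test the genotype.

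Among the named classes, Lepr was highest in papilla-like cells of the control and in fibroblast-like cells of the mutant libraries. Blood endothelial-like cells were not a named class of the unsorted libraries in the main clustering, so their level is not given. At Leiden resolution 1.4 they were named, with a mean share of 0.608% in the control and 0.727% in the mutant libraries. Lepr encodes the receptor for the adipocyte hormone leptin. The series title names this receptor as a mark of the follicle mesenchyme, and the comparison asks where its mRNA lay. In papilla-like cells Lepr (chromosome 4, 101717404 to 101815352 on the plus strand) stood at 96.8 and 85.7 CPM in the control and at 65.6 and 57.8 CPM in the mutant libraries. In fibroblast-like cells it stood at 57.2 and 51.9 CPM in the control and at 193 and 163 CPM in the mutant libraries. Lymphatic endothelial-like cells held 53.7 and 53.0 CPM in the control and 51.5 and 48.4 CPM in the mutant libraries. Dermal sheath-like cells, from the contractile layer around the follicle, held 21.8 and 19.9 CPM in the control and 34.4 and 40.1 CPM in the mutant libraries. Across all 4 libraries, papilla-like sums were not called different from fibroblast-like sums (log2 difference -0.82 ± 0.449, SE, edgeR adjusted p = 0.141, papilla-like higher in 2 of 4 libraries). The levels per library above are plain CPM, whereas these differences come from TMM-scaled sums. In the control libraries alone the difference was 0.34 ± 0.0945 (edgeR adjusted p = 6.4e-04), with TMM-scaled means of 79.7 CPM in papilla-like and 63.0 CPM in fibroblast-like cells. In the mutant libraries alone, a comparison added after the data were seen, it was -1.91 (edgeR adjusted p = 9.4e-11). Leaving out control library 1 or 2 moved the difference to -1.22 or -1.21, and leaving out mutant library 1 or 2 to -0.38 or -0.40. It was -0.44 at Leiden resolution 0.6, and -0.36 without the sub-clusters held almost wholly by 1 genotype, an alternative added after the data were seen. The mean TMM-scaled fibroblast-like level was 77.8 CPM without those sub-clusters and 134 CPM with them.

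Shares of cells with a Lepr UMI followed the same order. After thinning to 2000 UMIs, 16.9% and 14.4% of papilla-like cells held one in the control libraries and 12.4% and 10.2% in the mutant libraries. In fibroblast-like cells the share was 8.55% and 8.07% in the control and 23.9% and 21.4% in the mutant libraries. Basal keratinocyte-like cells, used as background, gave 0.432% and 0.215% in the control and 0.589% and 0.350% in the mutant libraries at the same depth. Their median before thinning was 17330 UMIs in control library 1, against 4593 in papilla-like cells of that library.

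**Figure D1:**
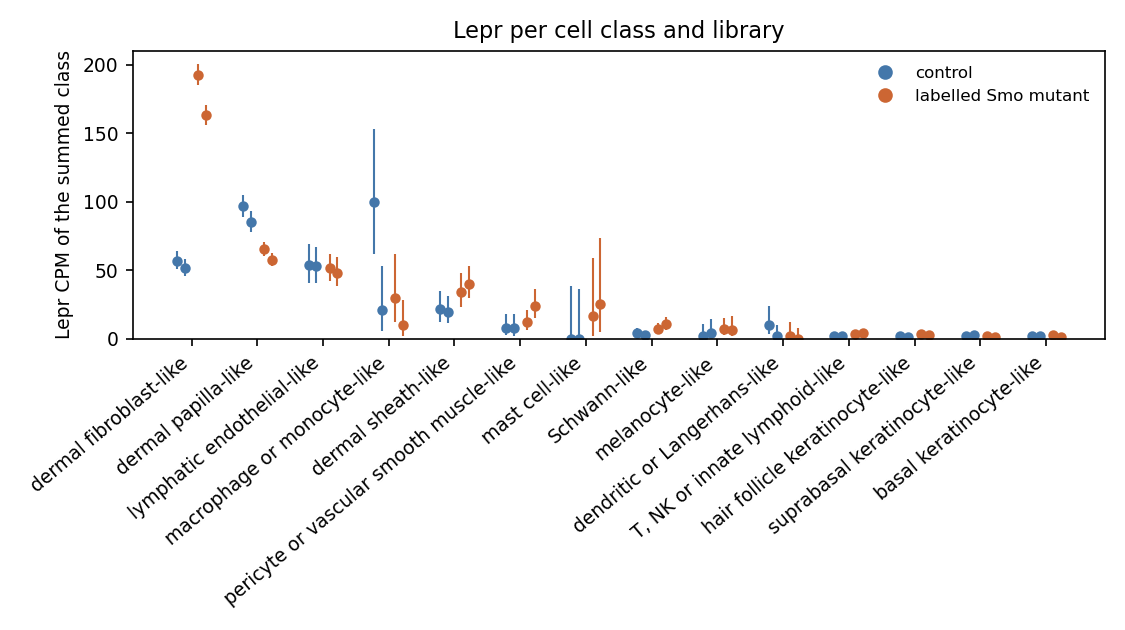
Lepr level (CPM) per named cell class and library, with bars for exact 95% Poisson intervals of the count. The papilla-like points of the control libraries lie at 96.8 and 85.7 CPM and the fibroblast-like points of the mutant libraries at 193 and 163 CPM.

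Most of the sorted GFP-positive cells carried papilla markers. Of 432 cells, 275 were papilla-like (63.7%, exact Clopper-Pearson 95% interval 58.9 to 68.2), 74 fibroblast-like (17.1%, 13.7 to 21.0) and 59 blood endothelial-like (13.7%, 10.6 to 17.3). Basal keratinocyte-like cells numbered 14 and T, NK or innate lymphoid-like cells 10. Lepr stood at 279 CPM (exact Poisson 95% interval 240 to 323) in the papilla-like, 240 CPM (168 to 332) in the fibroblast-like and 170 CPM (119 to 235) in the endothelial-like sums. The lymphoid-like sum held 0 Lepr UMIs of 26566, which allows a level of up to 113 CPM. The reporter eGFP stood at 6637 CPM in papilla-like and 10020 CPM in endothelial-like cells. Crabp1, a retinoic acid-binding papilla marker, reached 6826 CPM in papilla-like cells. This marker was not confined to them in the unsorted control libraries. There its TMM-scaled level was 1001 and 1022 CPM in papilla-like and 632 and 635 CPM in fibroblast-like cells. The papilla-like share depended on the resolution of the clustering, and at 1.4 it was 30.1% with 33.8% of the cells unnamed.

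In papilla-like cells of the mutant libraries 4 of 10 Hedgehog target genes rose, alongside 9 of 15 hair growth signals, 5 of 8 secreted Wnt inhibitors, 7 of 17 collagens and 8 of 11 contractile genes. The comparison asks what differs in the mesenchymal niche between the control libraries and those labelled Smo+/-. Which allele the mutant libraries carry was not settled here. Hhip, a decoy receptor that binds Hedgehog ligands, rose from 18.0 to 200.2 CPM (log2 change 3.47 ± 0.0905, SE, n = 2 per genotype, edgeR adjusted p = 1.6e-18). Ptch1, the Hedgehog receptor, rose from 48.1 to 234 CPM (2.29 ± 0.09), and Gli1, the transcription factor that the pathway induces, from 17.8 to 67.7 CPM (1.93 ± 0.103). The summed level of Hhip, Ptch1 and Gli1 was 1726 CPM in a sub-cluster of 578 mutant cells and 234 CPM in the other papilla-like cells of the mutant libraries. Without the sub-clusters held almost wholly by 1 genotype, an alternative added after the data were seen, Ptch1 (0.80) and Gli1 (0.68) stayed under the fold minimum and Hhip (2.03) was called. Those sub-clusters were picked by genotype, so a smaller difference without them is partly built in. The full comparison called 749 of 13172 genes, 527 higher and 222 lower, and 242 of the higher and 167 of the lower genes stood at 0.25 or more of their level in the highest class.

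**Figure D2:**
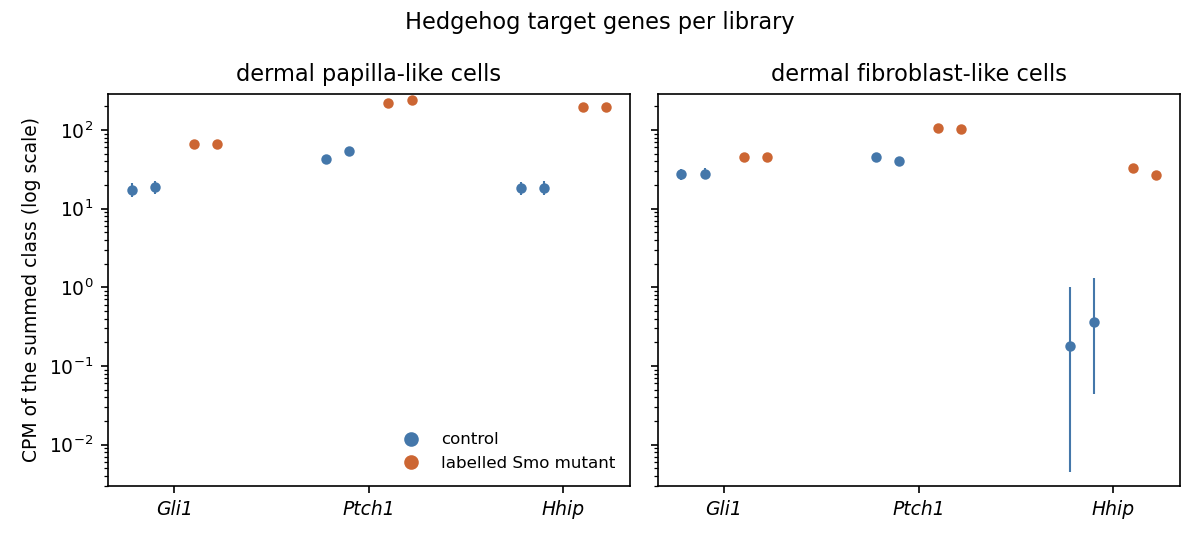
Levels of Gli1, Ptch1 and Hhip (CPM, log axis) per library in papilla-like and fibroblast-like cells, with bars for exact 95% Poisson intervals of the count. In papilla-like cells all 3 genes lie higher in both mutant than in both control libraries.

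Of 10 Hedgehog targets tested in papilla-like cells, 4 rose and none fell (camera adjusted p = 0.0159, and 4 adjusted over the list alone). The list of hair growth signals had 9 of 15 higher (camera adjusted p = 2.2e-06, and 9 adjusted over the list alone). Among them Igf1, a growth factor for follicle keratinocytes, rose by a log2 change of 3.02, Wnt5a, a noncanonical Wnt ligand, by 2.67, and Scube3, a secreted protein that the papilla makes in growing follicles, by 2.11. Rspo1, which amplifies Wnt signals, changed by 1.76, Fgf7 by 1.24, and Noggin (Nog), a Bmp antagonist, by 1.03. Secreted Wnt inhibitors had 5 of 8 higher (camera adjusted p = 0.0159, and 5 adjusted over the list alone), with Wif1 rising from 114 to 866 CPM, Sostdc1 by 2.69 and Frzb by 2.16. With an estimated correlation the adjusted p was 0.602 for each of these 3 lists. Notum, a secreted enzyme that inactivates Wnt ligands and is itself a Wnt target, fell from 729 to 158 CPM (log2 change -2.21 ± 0.0639, edgeR adjusted p = 8.2e-18), and Wnt10b fell by 1.5 on the same scale.

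Collagens had 7 of 17 higher in papilla-like cells (camera adjusted p = 1.4e-06, and 7 adjusted over the list alone). Col14a1 rose from 1.5 to 126 CPM, Col11a1 from 7.0 to 52.1 CPM and Col1a1 from 169 to 473 CPM. Col14a1 stood at 0.865 of its level in the highest class, but Col11a1 at 0.195 and Col1a1 at only 0.0196. Smooth muscle and contractile genes had 8 of 11 higher (camera adjusted p = 2.2e-07, and 8 adjusted over the list alone), with Myl9 changing by 2.38 and Acta2, smooth muscle actin, by 2.14. Chemokines and cytokines had 8 of 18 higher (camera adjusted p = 1.9e-06, and 8 adjusted over the list alone), with Lif at 1.67 and Il6 at 1.60. With an estimated correlation the adjusted p was 0.602 for each of these 3 lists. Markers of other cells moved with these groups, as 6 of 10 fibroblast markers and 6 of 10 dermal sheath markers rose. Myl9, Lif and Il6 stood at 0.0817, 0.0969 and 0.00974 of their level in the highest class. RNA carried over from other cells was not tested in papilla-like cells. It stays open as a source of the rises in genes at such low levels, Col1a1 and Col11a1 among them. Among genes that passed the naming rule, the largest falls were those of Gt(ROSA)26Sor, the transcript of the reporter locus (103 to 4.38 CPM), Rasgrf1 (22.2 to 1.00 CPM), Col6a6 (116 to 9.81 CPM) and Lmcd1 (84.4 to 12.4 CPM), and Nrn1 also fell (443 to 109 CPM). The control sums include the sub-cluster of 147 control and 3 mutant cells. Its median was 21720 UMIs, against 3870 in the other papilla-like control cells. That sub-cluster was not left out alone, so its part in these falls stays open.

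Of 16 immediate early and heat shock genes 3 fell in papilla-like cells, with Hspa1a going from 8178 to 3022 CPM and Hspa1b and Dnajb1 by log2 changes of -1.28 and -1.05, and the list was lower (3 adjusted over the list alone, camera adjusted p = 5.1e-07). With an estimated correlation the adjusted p was 0.602. Without the sub-clusters held almost wholly by 1 genotype, 539 genes were called in papilla-like cells, Hspa1a, Hspa1b and Dnajb1 stood at -0.19, -0.36 and -0.09, and Acta2 and Nog at 0.66 and 0.46, under the fold minimum. Igf1 (1.83), Wif1 (1.54), Scube3 (1.33) and Notum (-1.52) were still called. Leaving out control library 2 put Nog at 0.97, under the fold minimum.

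In fibroblast-like cells of the mutant libraries 4 of 11 contractile and 4 of 11 adipogenic genes rose, Lepr among the latter, and Gas6 fell. Lepr rose from 54.0 to 180 CPM (log2 change 1.74 ± 0.0917, SE, n = 2 per genotype, edgeR adjusted p = 7.3e-08). Acta2 rose from 13.7 to 106 CPM (2.95 ± 0.12) and Fabp4, a fatty acid-binding protein of adipocytes, from 2.75 to 81.3 CPM (4.88 ± 0.383). Gas6, a ligand of TAM receptor kinases, fell from 640 to 207 CPM (-1.63 ± 0.0698). The comparison called 248 of 12635 genes, 180 higher and 68 lower. Without mutant library 1 or 2, where the lone mutant library is assumed to vary like the controls, the count was 43 or 19, and without the sub-clusters held almost wholly by 1 genotype it was 68, with Lepr (0.65), Acta2 (0.90) and Fabp4 (0.91) under the fold minimum.

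Of 11 Hedgehog targets tested in fibroblast-like cells, 3 rose, Hhip and Ptch1 among them, and 3 also did adjusted over the list alone. The list did not pass (camera adjusted p = 0.0519, and 0.0477, 0.0477 and 0.0484 without control library 1, mutant library 1 and mutant library 2, but 0.146 without control library 2), and with an estimated correlation the adjusted p was 0.602. By fry, which asks whether the list changed at all and not whether it changed more than other genes, the adjusted p was 0.0365. Hhip went from 3 UMIs in the control to 758 in the mutant libraries, a ratio of 112 (95% counting interval 38.1 to 543). Ptch1 went from 42.1 to 106 CPM (log2 change 1.33). Gli1 was at 27.4 and 46 CPM, a log2 change of 0.75 under the fold minimum. Ptch1 was not called without mutant library 2 (1.36, edgeR adjusted p = 0.063). Without the sub-clusters held almost wholly by 1 genotype, Ptch1 stood at 0.16 and Gli1 at -0.09, and Hhip at 3.32 was still called.

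Adipogenic genes had 4 of 11 higher in fibroblast-like cells, Fabp4, Lepr, Cd36 and Pparg (camera adjusted p = 0.00263, and 4 adjusted over the list alone). Contractile genes had 4 of 11 higher (camera adjusted p = 1.3e-04, and 4 adjusted over the list alone). Markers of other cells moved with them, since 2 of 3 adipocyte and 3 of 10 dermal sheath markers rose (camera adjusted p = 0.00183 and 0.0128). Collagens were lower as a list of 18, although none passed singly (camera adjusted p = 0.0106, and 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.602 for each of these lists. Other rises were those of Gpc3, a glypican of the cell surface (122 to 549 CPM), Igfbp4, which binds insulin-like growth factors (264 to 1127 CPM), Lrrc15 (40.2 to 232 CPM), Slco2a1, a prostaglandin transporter (24.7 to 147 CPM), Fbn2 (11.5 to 48.9 CPM), and Cxcl12, a chemokine (117 to 330 CPM). Cxcl12 was not called without mutant library 2 (1.55, edgeR adjusted p = 0.068), Pparg not without mutant library 1 (2.38, 0.055) or 2 (2.67, 0.063), and Cd36 not without control library 2 (0.85, 0.236), mutant library 1 (1.71, 0.369) or mutant library 2 (1.73, 0.351). Of the contractile genes Acta2 was called without any 1 library, whereas Actg2 was not called without mutant library 1 (2.24, 0.109) or 2 (3.40, 0.0647), Myh11 not without mutant library 1 (0.97, 0.268) or 2 (1.58, 0.111), and Tagln not without control library 2 (0.99), mutant library 1 (0.75, 0.0755) or mutant library 2 (1.32, 0.0598). Without the sub-clusters held almost wholly by 1 genotype, Slco2a1 stood at 0.70, Fbn2 at 0.63, Cxcl12 at 0.41, Pparg at 0.61, Igfbp4 at 0.09, Gpc3 at -0.28 and Lrrc15 at -0.68, none of them called.

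In basal keratinocyte-like cells of the mutant libraries 4 of 11 interferon-induced genes and 7 of 21 chemokines and cytokines rose, and Ly6d fell. Such cells form the proliferating layer of the epidermis. Cxcl9 and Cxcl10, chemokines that attract T cells, rose from 3.25 to 61.7 CPM (log2 change 4.24 ± 0.19, SE, n = 2 per genotype, edgeR adjusted p = 9.0e-10) and from 46.5 to 407 CPM (3.13 ± 0.0595). Gbp2, an interferon-induced GTPase, rose from 8.30 to 107 CPM (3.69 ± 0.0616). Ly6d, a surface protein of keratinocytes, fell from 6221 to 1870 CPM (-1.73 ± 0.0325). The comparison called 378 of 14572 genes, 320 higher and 58 lower, but only 27 of the higher and 27 of the lower genes stood at 0.25 or more of their level in the highest class. Gbp2 was not among those 27 higher genes.

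The interferon list had 4 of 11 higher in basal keratinocyte-like cells (camera adjusted p = 0.00372, and 4 adjusted over the list alone), including Iigp1 (3.65) and Ifit1 (1.48). Chemokines and cytokines had 7 of 21 higher (camera adjusted p = 1.1e-05, and 7 adjusted over the list alone), with Ccl2 rising from 12.7 to 39.8 CPM. Ccl2 stood far higher in lymphatic endothelial-like cells, at 522 CPM in the control and 1697 CPM in the mutant libraries. Proliferation genes were lower as a list of 20 (camera adjusted p = 5.2e-07), of which 1 passed singly, also adjusted over the list alone, the mitotic kinase Aurkb (-1.07). Without mutant library 1 Aurkb stood at -0.96, under the fold minimum. Growth factors with rises were Nrg1, a ligand of ErbB receptors (85.8 to 205 CPM), and Pdgfb (28.0 to 63.1 CPM), and the natriuretic peptide gene Nppb went from 108 to 365 CPM. Hedgehog targets had 4 of 10 higher (camera adjusted p = 0.00263, and 5 adjusted over the list alone), at levels such as 0.472 and 1.34 CPM for Gli1. With an estimated correlation the adjusted p was 0.602 for each of these 4 lists. Markers of other cells moved with them, since 9 of 10 fibroblast markers and 4 of 6 mast cell markers rose (camera adjusted p = 8.8e-08 and 0.00900, and 0.602 for both as adjusted p with an estimated correlation).

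Hair follicle keratinocyte-like cells showed few differences, and Hedgehog targets were not among them. Of 8 Hedgehog targets tested, 0 were called by edgeR, also adjusted over the list alone (camera adjusted p = 0.793, and adjusted p = 0.879 with an estimated correlation). Ptch1 had a log2 change of 0.24 ± 0.131 and Gli1 of -0.11 ± 0.231. The comparison called 71 of 12609 genes, 51 higher and 20 lower. Prss22, a serine protease, rose from 6.69 to 47.6 CPM (log2 change 2.83 ± 0.116, SE, n = 2 per genotype, edgeR adjusted p = 8.2e-07). Hist1h2al, annotated as a pseudogene of a histone family with near-identical copies, went from 1002 UMIs to 2, a ratio of 330 (95% counting interval 91.1 to 2729), and it was lower in 8 of 9 classes tested. The count was 7 without mutant library 1 and 14 without mutant library 2. The class depended on the clustering, and with the whole Hedgehog list left out of it, an alternative added after the data were seen, 137 genes were called, 32 of them shared with the 71, and the class held 3.12% of control and 2.22% of mutant cells.

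In this follicle class, markers of mesenchymal cells moved too, with 2 of 10 fibroblast and 2 of 9 papilla markers higher (camera adjusted p = 2.5e-05 and 0.00325, and 0.602 for both as adjusted p with an estimated correlation). Collagens had 1 of 18 higher, Col3a1 (camera adjusted p = 6.9e-04, and 2 adjusted over the list alone), and with an estimated correlation the adjusted p was 0.602. Inhba, a subunit of activin, rose by a log2 change of 1.90, Wif1 by 1.32 and the matrix protease Mmp3 by 2.00, and the peptide transporter Slc15a2 changed by -1.15. Inhba and Slc15a2 were not called without mutant library 1 (1.66 and -1.19, edgeR adjusted p = 0.058 for both). Mmp3 was not called without mutant library 1 (1.93, 0.252) or 2 (2.07, 0.201), Wif1 not without mutant library 1 (1.12, 0.168) or 2 (1.51, 0.066), and Col3a1 not without control library 1 (0.90), mutant library 1 (1.05, 0.131) or mutant library 2 (1.03, 0.0902).

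Gt(ROSA)26Sor fell in nearly every class of the mutant libraries where it was tested. The gene (chromosome 6, 113067428 to 113077333 on the minus strand) marks the locus that carries the reporter, whose tomato mRNA stood at 823 CPM in the control and 826 CPM in the mutant libraries. It was called lower in 10 of 11 classes, with log2 changes from -5.23 in suprabasal keratinocyte-like to -2.33 in lymphatic endothelial-like cells, and in pericyte-like cells it was at -3.28 and not called. In fibroblast-like cells it was not called without mutant library 2 (-3.47, edgeR adjusted p = 0.068). Prss22 was higher in 11 of 11 classes, Hist1h2al lower in 8 of 9 (median log2 change -8.25), and Ly6d lower in 8 of 14.

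**Figure D3:**
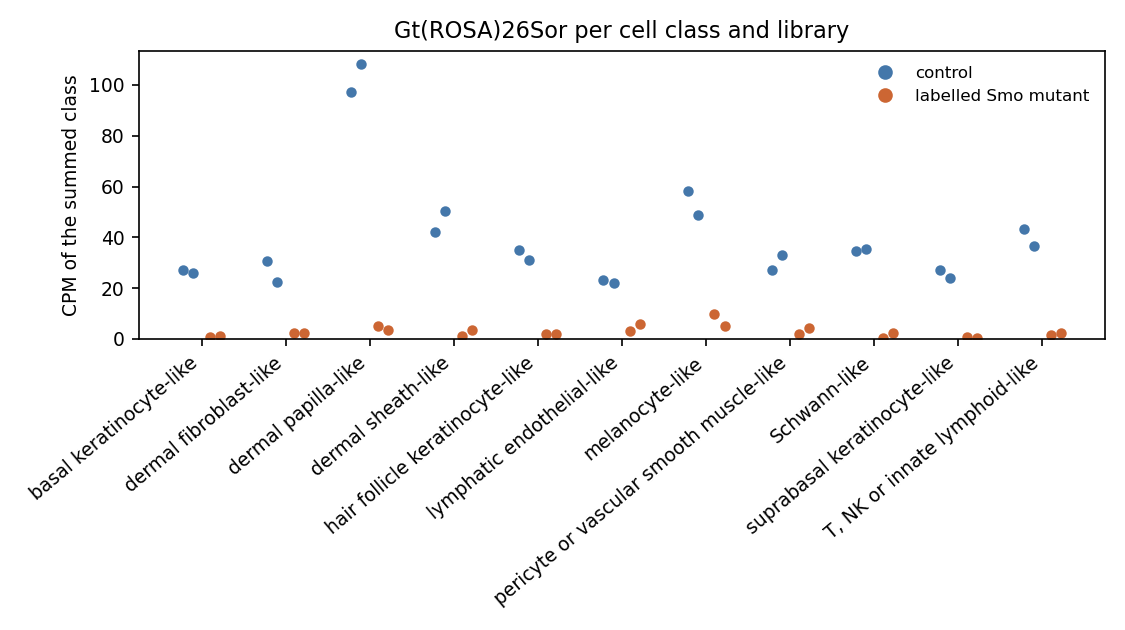
Gt(ROSA)26Sor level (TMM-scaled CPM) per cell class and library. Papilla-like cells went from a mean of 103 CPM in the control to 4.38 CPM in the mutant libraries.

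Among the remaining classes, edgeR called 418 of 11755 genes in T, NK or innate lymphoid-like cells, 161 higher and 257 lower, and 191 of 12289 in suprabasal keratinocyte-like cells. Dermal sheath-like cells had 70, lymphatic endothelial-like cells 41, mast cell-like cells 37, Schwann-like cells 11, pericyte-like cells 7, melanocyte-like cells 6 and dendritic-like cells 2. Markers of other cells were among these calls. Only 4 of 34 higher genes in mast cell-like and 16 of 153 in suprabasal keratinocyte-like cells stood at 0.25 or more of their level in the highest class. Higher genes below that level included keratinocyte genes such as Krt16 and Sfn in mast cell-like cells. In suprabasal keratinocyte-like cells they included fibroblast genes such as Col1a1 and Dcn. In macrophage-like cells edgeR called 0 of 3088 genes, with 181 at an unadjusted p under 0.05, and no other tool was run on this class.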

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

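Among the tests weighed here, those on the Rosa26 locus, those on doublets in sub-clusters and those that split the sub-clusters by genotype were chosen only after the result was seen.

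The genotype difference itself differed between papilla-like and fibroblast-like cells for 2549 of 13790 genes at an adjusted p under 0.05, by an interaction term in edgeR, among them 5 of 8 genes looked up (Lepr, Smo, Scube3 and 5 others of the Hedgehog pathway). Lepr differed by a log2 value of -2.24 (adjusted p = 4.8e-16), from log2 changes of -0.53 in papilla-like and 1.74 in fibroblast-like cells. Gli1 differed by 1.21 and Ptch1 by 0.98, with the larger change in papilla-like cells. Hhip differed by -3.27, with 3 control UMIs in fibroblast-like cells behind it, and Gli2 by -0.64. Without the sub-clusters held almost wholly by 1 genotype, Lepr differed by -1.21, Gli1 by 0.78 and Ptch1 by 0.66, still under 0.05, whereas Hhip at -1.27 (adjusted p = 0.281) and Gli2 at 0.05 (adjusted p = 0.948) were not.

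YFP, a reporter that the labels do not mention for these mice, was counted at 8.84 CPM in mutant library 1 and 8.91 CPM in mutant library 2, against 0 UMIs in kept control cells, which allows up to 0.0220 and 0.0217 CPM. It stood at 52.2 and 56.2 CPM in papilla-like and at 27.0 and 26.2 CPM in fibroblast-like cells of the mutant libraries, and at 0.398 and 0.606 CPM in basal keratinocyte-like cells. Its sequence is nearly identical to that of eGFP, so reads may be shared between them, yet control libraries, which also held eGFP, gave 1 YFP UMI over all deposited barcodes.

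Gt(ROSA)26Sor fell in 10 of 11 classes. A changed mix of cell classes is argued against by the smallest fall within the tested classes, -2.33, while tomato, the reporter at the same locus, stood at 823 CPM in the control and 826 CPM in the mutant libraries. Less of it in free RNA as the whole cause is argued against by the fall in 10 of the 11 classes (1.18 UMIs per cell in papilla-like cells), which exceeded 0.124 UMIs per cell, the upper 95% limit of the class with the lowest level in the control. A further insertion at Rosa26 that carries YFP, such as a Cre-activated form of Smo, was put forward because of these values, was not tested and would differ from the Smo+/- of the labels. Differences in genetic background between animals also stay open, as untested.

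The rises in basal keratinocyte-like cells may stem from free RNA of other cells. For 293 genes below 0.25 of their highest class, the rise exceeded that in the other cells by a median log2 value of 0.67 (quartiles 0.437 to 1.08). For 27 genes at or above 0.25 it exceeded it by 0.88 (quartiles 0.658 to 1.46). Both medians lie between the bounds set for and against free RNA, so the explanations cannot be told apart. A change in the keratinocytes themselves stays open.

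The sub-clusters held almost wholly by 1 genotype could be doublets or stressed cells. Over all 4 of them neither was decided, with a lowest UMI ratio to other cells of the class of 0.882 and a smallest difference in stress genes, in either direction, of 1.03-fold. In the 3 mutant sub-clusters the stress ratios were 0.972, 0.713 and 0.512, none above the other cells, but the last was 1.95-fold apart and a difference in stress stays open. The UMI ratio of 0.882 (upper 95% limit 0.927) was that of the largest of them and argues against doublets there. In the other 2 the highest UMI ratio of 1.34 lay between the bounds of 1.2 and 1.5 and leaves doublets open. In the order of the stress ratios, YFP stood at 132, 70.2 and 141 CPM, against 37.8, 7.42 and 43.5 CPM in the other mutant cells of the class. Summed Gli1, Ptch1 and Hhip stood at 1726, 419 and 639 CPM, against 234, 75.0 and 475 CPM. A response to the genotype stays open and was not tested. The control sub-cluster had a stress ratio of 2.72, in line with dissociation stress, and a UMI ratio of 5.61, while Krt14 stood at 161 against 218 CPM in the other cells, so doublets stay open there.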

How the results depend on the processing

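The alternatives without sub-clusters held almost wholly by 1 genotype, with the whole Hedgehog target list left out of clustering, with crossed replicate numbers as a block, and with the mutant libraries alone were chosen after seeing the data. Of 159 called named genes, 82 kept their call in every alternative followed gene by gene, 48 of 66 in papilla-like, 27 of 46 in basal, 4 of 35 in fibroblast-like and 3 of 12 in follicle cells. Those alternatives were RLE size factors, the replicate block, no low-count filter, DESeq2 and each library left out. The clustering without the whole Hedgehog list and, in papilla-like and fibroblast-like cells, the sums without the sub-clusters were also among them. Stricter cell filters, kept doublets, other Leiden resolutions and glmTreat were followed only as gene counts. A gene without a value in an alternative was not scored there. RLE size factors left every named call in place. Leaving out the sub-clusters kept 5 fibroblast-like named calls, lost 22 and changed the sign of 4. These sub-clusters were picked by genotype, so that loss is partly built in. Leaving the whole Hedgehog list out of clustering kept 35 of 35 fibroblast-like and 66 of 66 papilla-like named calls, 37 of 44 basal and 6 of 11 follicle calls that could be tested. The low number of libraries and the fold minimum both limit what can be called, and the causes of the changes below were not tested.

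Against 248 fibroblast-like, 749 papilla-like, 71 follicle and 378 basal genes called, 1840, 3754, 343 and 3657 passed with no fold minimum, and at 0.25 or more of the highest class 124, 409, 29 and 54. DESeq2 called 152, 491, 36 and 183, and glmTreat 66, 255, 9 and 73. No low-count filter gave 163 fibroblast-like and 4 follicle genes. Leaving out 1 library gave 19 to 327 fibroblast-like and 7 to 83 follicle genes. Without the sub-clusters 68 fibroblast-like genes were called. Follicle counts were 133 and 134 at Leiden resolutions 0.6 and 1.4, and 137 with the whole list left out, so the main clustering stood apart from these 3. With the replicate block the counts were 297, 773, 106 and 448, and across genes the deviations of libraries with the same number correlated by 0.226, 0.0310, 0.0658 and -0.315.

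The Hedgehog list in fibroblast-like cells, at an adjusted p of 0.0519, had one of 0.0421 with no low-count filter, 0.0477 to 0.146 without 1 library, and 0.0941 with the replicate block. By fry, which tests against no change where camera tests against other genes, it was 0.0365. Lepr in papilla-like against fibroblast-like cells, at -0.82, was 0.34 in control libraries only, -1.91 in mutant libraries only and -1.22 to -0.38 without 1 library. It was -0.44 at resolution 0.6 and -0.36 without the sub-clusters.

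Differences in class share, in percentage points, of 5.20 (fibroblast-like), 9.01 (papilla-like), -2.73 (follicle) and -6.36 (basal) became 7.52, 11.5, -3.49 and -8.07 at no more than 5% mitochondrial UMIs. Without the sub-clusters they were 2.97 and 5.72 for the first pair. At resolution 0.6 they were 8.53 (papilla-like) and -0.896 (follicle), and at 1.4 -0.902 (follicle). With the whole list left out they were -0.896 (follicle) and -5.68 (basal), and at 1000 genes or more -6.85 (basal). The sorted papilla-like share of 63.7% was 30.1% at 1.4.

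Without the sub-clusters, these fibroblast-like values changed sign: Gli1 -0.0858, Gli2 -0.14, Gpc3 -0.28, Lrrc15 -0.68, Postn -0.30, Smo -0.048 and Tagln -0.21, as did Gli2 (-0.11) and Gli3 (0.0137) in papilla-like cells. With the whole list left out, so did Gli2 (-0.11) and Lepr (-0.0904) in basal and Smo (0.0878) in follicle cells.

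Leaving out 1 library changed the sign of 6 named values. In basal cells Gli2 ranged from -0.0366 (without control library 2) to 0.11 (without control library 1), and Lepr from -0.27 (without mutant library 1) to 0.35 (without mutant library 2). In papilla-like cells Areg ranged from -1.64 (without control library 2) to 0.0874 (without control library 1). In follicle cells Gli1 ranged from -0.39 (without control library 1) to 0.24 (without control library 2), Gli2 from -0.21 (without mutant library 1) to 0.0741 (without mutant library 2), and Smo from -0.196 (without control library 1) to 0.0857 (without control library 2).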

Other observations

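The genes in the next 2 paragraphs were picked after their values were seen, and the test by YFP was changed after its first result was seen. In T, NK or innate lymphoid-like cells of the mutant libraries Cxcr3, the receptor for Cxcl9 and Cxcl10, rose from 31.1 to 65.2 CPM (log2 change 1.07 ± 0.0999, SE, n = 2 per genotype, edgeR adjusted p = 3.2e-07), the co-receptor Cd4 from 10.6 to 23.7 CPM and the scavenger-like receptor Cd6 from 75.8 to 158 CPM. The chemokine receptor Ccr10 rose by 1.47 and the adhesion receptor Cd226 by 1.16. Asph, a hydroxylase of the endoplasmic reticulum, fell from 409 to 78.9 CPM (-2.38), the kinase subunit Pik3cd from 178 to 53.2 CPM and the guanylate cyclase receptor Gucy2c from 241 to 93.1 CPM. The class joins several kinds of lymphocyte, and a different mix of them was not tested.

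In dermal sheath-like cells of the mutant libraries Vcam1, an adhesion molecule, rose from 201 to 499 CPM (log2 change 1.30 ± 0.13, SE, n = 2 per genotype, edgeR adjusted p = 2.2e-19), Tnc, tenascin C, from 184 to 408 CPM and Ltbp1, which binds latent TGF-beta, from 27.2 to 80.3 CPM. Gli1 (0.13) and Ptch1 (58.4 against 58.0 CPM) were not called. Of the same Hedgehog target list, Ccnd1 was called higher (1.48) and Osr2 lower (-1.17). In lymphatic endothelial-like cells Angpt2, a ligand of the receptor Tie2, rose from 128 to 280 CPM and Csf3, the granulocyte growth factor, from 51.3 to 194 CPM, and Igfbp5 fell from 1489 to 535 CPM. In Schwann-like cells Kitl, the ligand of Kit, rose from 296 to 606 CPM.

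The reporter eGFP stood at 59.7 and 51.0 CPM in fibroblast-like cells of the control and at 397 and 399 CPM in those of the mutant libraries. This class includes the sub-cluster of 4 control and 502 mutant cells, where YFP stood at 70.2 CPM, against 7.42 CPM in the other mutant cells. Reads may be shared between eGFP and YFP, and the part of this sub-cluster in the eGFP difference was not tested. In papilla-like cells eGFP stood at 486 and 518 CPM in the control and at 479 and 458 CPM in the mutant libraries.

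A hypothesis was that recombined cells, marked by YFP, carry the rise of Hedgehog targets in papilla-like cells. In mutant library 1 the summed Gli1, Ptch1 and Hhip level was 796 CPM in 279 cells with a YFP UMI and 316 CPM in 1030 cells without one, a ratio of 2.52 (2.38 to 2.67, 95% interval for counting error only). In mutant library 2 it was 788 against 331 CPM in 292 and 991 cells, a ratio of 2.38 (2.25 to 2.52). Cells without a YFP UMI also stood above the 77.9 and 91.5 CPM of papilla-like cells in the control libraries, so the rise was not confined to cells in which YFP was counted. Cells with a YFP UMI were also deeper, with medians of 7469 against 5354 and 7006 against 5233 UMIs, and a recombined cell could lack a YFP UMI by chance, so the hypothesis was not decided.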
